A study of Homo sapiens with 6 samples.

How the data were processed

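Polyadenylated RNA was sequenced from 6 samples of HLF, a human liver cancer cell line, in 2 groups of 3. Per the labels' protocols, the cells carried a CRISPR/Cas9 knockout of BAF155, the SWI/SNF chromatin remodelling subunit encoded by SMARCC1, and re-expressed either wild type BAF155 or the R1064K mutant from a lentivirus. RNA was extracted with a Monarch kit and strand-specific libraries were made by a service provider, per the labels' protocols. The labels number the samples of each group by 3 batches. They do not say whether the samples of a group came from separate cultures. The deposited p-values of genes therefore measure the spread between these samples, which may be technical.

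Per the submitters' processing notes, the authors used STAR, Salmon, deepTools and DESeq2 with build hg38; versions, order, settings and the model formula are not given in the sources used here. The values analysed are one comparison table made by the authors, with a row per gene and 37951 rows. Per the file headers, it gives the mean level as a signal per gene (the mean over all samples of counts divided by size factors, as that column name is used in DESeq2 output), the log2 fold change with its standard error, the p-value and the adjusted p-value, and the position and symbol of the gene. Values per sample were not analysed here, so no model was refitted, and no value below carries an SD or n of its own. The deposited log2 folds appear shrunken towards 0, since some rows with a small p-value have a fold near 0. Among the rows past the threshold, 28 had a fold smaller than its standard error, and 25 of those had a mean level under 100. The table does not state the direction of its folds. Its name puts wild type first, and a positive fold is therefore read as higher with wild type BAF155; if it was coded the other way, every direction given here inverts.

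The mean level was 0 in 17980 rows, and the other 19971 had a p-value. An adjusted p was given for 13701 rows, of which the lowest mean level was 7.99; the other 6270 rows with a p-value were left out of all counts of calls. Totals per sample were not analysed here. The mean levels sum to 28257078 normalized counts. Among the rows with the lowest levels, 6 recurring values (195 to 285 rows each) correspond to 1 read in 1 library and give size factors of 0.893 to 1.21, a ratio of 1.36 between the highest and the lowest. They are not tied to samples or groups. Of the 3635 rows below a level of 1, 60.0% were sums of whole reads at those factors (tolerance 1e-06, up to 7 reads), so reads per sample were not recovered.

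A row was called at a deposited adjusted p under 0.05. For lists and chromosomes, 1 row per symbol on the primary chromosomes was kept, 13149 symbols with an adjusted p, of which 10751 had a mean level of at least 100. Rows on other contigs numbered 2878 and held 35 of the calls. For lists they were not added to the primary row of the same symbol. A low primary level may therefore hold only part of a gene's reads. Examples, named outside the rule given below, are RPS9 (level 27.8), HLA-B (13.1) and HLA-C (79.4). GENCODE release 29 holds 97.7% of the symbols and gives the same position and symbol for 77.3% of the primary rows. Its gene models, with older symbols matched through gene identifiers, served for GC content and length. Coordinates are the table's own, on hg38. How reads shared between paralogs or pseudogenes were divided is not given in the sources used here, so values of ribosomal protein, histone, metallothionein, protocadherin and mitochondrial genes are uncertain to that extent.

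The rule for genes named in the text was set before the data were examined, as were 38 gene lists with 1109 entries. SMARCC1 and CARM1 are named always. Next come, among genes at a mean level of at least 100 past the threshold, the 12 with the largest folds and the 3 with the smallest p in each direction. In a list that passed its test or held at least 3 called members, up to 4 members with the smallest p are named, and up to 2 in any other. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be so. Of the list entries, 9 were not found and were not analysed here.

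Each list was set against the other symbols with limma 3.58.1 (cameraPR, R 4.3.3) on the deposited log2 fold divided by its standard error, with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over the 38 lists. The correlation could not be estimated without values per sample, so 0.05 was tried as well. Medians along chromosomes were set against 10000 random lists of the same size matched on mean level. This was done for 24 chromosomes, the mitochondrial genome included, and 253 windows of 10 Mb with at least 15 genes. Genes were at a level of at least 100, and p-values were adjusted within each family. List tests and random lists compare genes with other genes within 1 comparison. Their p-values do not measure whether a shift recurs across samples. Shares carry 95% exact Clopper-Pearson intervals, which treat genes as independent. Medians in the closing section carry 95% intervals from 10000 bootstrap draws of genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

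The steps that call genes and lists were tested on simulated data for the comparison of R1064K and WT. In 20 simulations over 13149 genes, 98.6% of 200 genes changed by a log2 fold of 1 were recovered and 5.37% of calls were false. A list shifted by 0.15 was called in 20 of 20, and 3.51% of the other lists were called. Simulated folds were drawn independently for each gene from its standard error, with p-values from the fold over that error. Deposited p-values depart from that ratio in some rows, and real genes may be correlated. These rates therefore check the working of the steps and do not give error rates for the deposited calls or the list tests. Alternatives tried were other thresholds on adjusted p, fold and mean level, adjustment over every p-value, and for the lists another correlation, ranks, the fold itself, a level minimum and centring. After the data were seen, counting 1 row per symbol, leaving out 3 chromosome segments, and a signed z from the p-value were added.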

Results

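Gene expression was measured by sequencing polyadenylated RNA from HLF cells, a human liver cancer line, in which BAF155 had been knocked out and then re-expressed as the wild type protein (3 samples) or as R1064K (3 samples). BAF155, the product of SMARCC1, is a core subunit of SWI/SNF (BAF) chromatin remodelling complexes. In R1064K a lysine replaces an arginine, and the series' design text describes this form as one that methylation does not reach. CARM1 is the arginine methyltransferase known to modify BAF155. The comparison asks which transcripts differ when that methylation is prevented, and the series title links that methylation to contacts of BAF155 with RNA processing factors. The values are those of the authors' deposited table, in which mean levels over the 6 samples sum to 28257078 normalized counts. Size factors read from its lowest levels span 0.893 to 1.21. Direction is given as the sign of the deposited fold. Positive is read as higher with wild type BAF155, from the order in the table's name, and all directions invert if it was coded the other way.

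SMARCC1 itself differed between the groups. Its row on chromosome 3 (47585269 to 47782106, minus strand, hg38) had a mean level of 7782 normalized counts and a log2 fold of 0.53 (SE 0.05), or 1.44-fold, with an adjusted p of 5.33e-23 in the authors' deposited table. A gene-level row does not separate lentiviral from endogenous transcripts, so this value does not measure the knockout, and the total SMARCC1 transcript was not matched between the groups. Among 26 BAF complex subunits tested, SMARCC1 was the 1 member past the threshold, also when adjusted over the list alone. The deposited fold of PBRM1, a subunit of the related PBAF complex, was 0.21 (SE 0.12, adjusted p 0.0909). CARM1 (chromosome 19, 10871513 to 10923070, plus strand, level 2999) had a log2 fold of -0.14 (SE 0.06) and an adjusted p of 0.0600 in the authors' deposited table. Of 10 arginine methyltransferases and partners tested, WDR77, the cofactor of PRMT5, was called (0.17, SE 0.06, adjusted p 0.0184). Adjusted over the list alone, 2 members were positive and 1, CARM1, was negative (adjusted p 0.0276 over the list). CARM1 lies at 10 to 20 Mb of chromosome 19, where the median of 188 genes was -0.04, past the random-list threshold. Neither list passed the limma list test (adjusted p 0.212 for BAF subunits and 0.362 for methyltransferases).

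Many transcripts differed, most by little. The authors' deposited table had 1372 of 13701 rows with an adjusted p under 0.05, of which 602 had a positive and 770 a negative fold; 2826 rows had an unadjusted p under 0.05. The median size of the called log2 folds was 0.28 (interquartile range 0.19 to 0.49), a change of 1.21-fold. At least 1.5-fold was reached by 272 rows and at least 2-fold by 131, of which 66.4% were positive against 43.9% of all calls.

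LRRTM4, a synaptic adhesion protein, had the largest log2 fold in the authors' deposited table among called genes at a level of at least 100 (6.65, SE 0.69, level 115). DSG2, a cadherin of desmosomes, followed at 4.14 (SE 0.10) and a level of 1927, with an adjusted p listed as 0. GFRA1, the co-receptor for GDNF, stood at 3.85 (SE 0.27), the sodium-calcium exchanger SLC8A1 at 3.74 (SE 0.53) and the surface glycoprotein THY1 at 3.54 (SE 0.66) in the authors' deposited table. FAM133A, FAM155A, MAMDC2, the glycosylation gene ALG14, the collagen COL5A2, the actin-binding CALD1 and FIGNL1 had deposited log2 folds from 2.43 down to 1.94. FAM155A lies on chromosome 13, where 87.4% of genes had a positive fold. ALDH1A1, which oxidises retinaldehyde (1.48, SE 0.05, adjusted p 2.31e-161), had the smallest p-value after DSG2 on this side in the authors' deposited table.

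On the negative side of the authors' deposited table, the largest log2 folds of called genes at a level of at least 100 were -2.97 (SE 0.28) for MAOA, which oxidises monoamines, and -2.77 (SE 0.25) for the glutamate transporter SLC1A1. CYP1B1, a cytochrome P450, had -2.01 (SE 0.07) at a level of 1993 and the smallest adjusted p on this side, 1.47e-168. Next were the stress-activated kinase gene MAP3K5 (-1.97, SE 0.13), DPYSL3 (-1.85, SE 0.22), the integrin-binding FERMT1 (-1.77, SE 0.26), PARP8 (-1.75, SE 0.28) and FAM107B (-1.70, SE 0.26) in the authors' deposited table. TDO2, which breaks down tryptophan, had a deposited log2 fold of -1.54, TMEM47 -1.45, TENM1 -1.44 and HPGD, which inactivates prostaglandins, -1.34. TXNIP, the thioredoxin-interacting protein, was at -1.27 (SE 0.06, level 5959, adjusted p 9.55e-84). Whether each of these genes differed in every sample or in every batch was not examined, since the table has no values per sample.

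**Figure D1:**
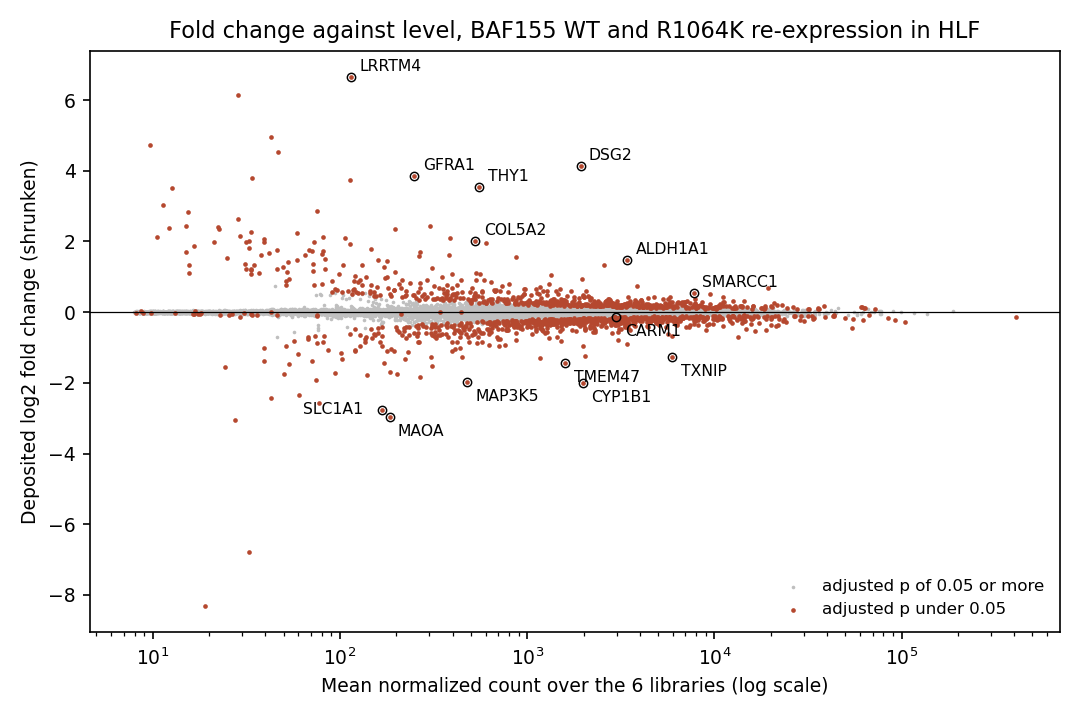
Each point is a row of the authors' deposited table with an adjusted p, by mean normalized count over the 6 libraries (log scale) and deposited log2 fold change; red points have an adjusted p under 0.05 and some of the genes named in the text are circled. DSG2 (4.14) and CYP1B1 (-2.01) stand out at levels of 1927 and 1993, SMARCC1 lies at 0.53, and grey points at low levels lie close to 0.

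Genes of DNA replication leaned positive. Of 32 tested S phase and DNA replication genes, 14 were called positive and 0 negative (16 positive when adjusted over the list alone), with a median log2 fold of 0.10 and a list-test adjusted p of 6.42e-08. They included the replicative helicase subunit MCM3 (0.28, SE 0.04), the maintenance methylation factor UHRF1 (0.25, SE 0.05), the flap endonuclease FEN1 (0.36, SE 0.07) and thymidylate synthase TYMS (0.20, SE 0.04) in the authors' deposited table. Genes of G2 and mitosis did not pass (adjusted p 0.951): of 29 tested, MKI67 was called positive (0.17, SE 0.05) and AURKA negative (-0.13, SE 0.04), the same counts as when adjusted over the list alone. Of 40 MYC target genes, 9 were called positive and 0 negative (10 adjusted over the list alone; median 0.06, list-test adjusted p 0.000302). Among them were the transferrin receptor TFRC (0.28, SE 0.05) and the ribosome assembly genes UTP20 (0.31, SE 0.06) and MRTO4 (0.25, SE 0.07), with the importin IPO4 at 0.19 (SE 0.07), in the authors' deposited table.

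Splicing regulators leaned positive, while core spliceosome genes did not pass. Of 45 tested hnRNPs and other splicing regulators, 13 were called positive and 1 negative, the same counts as when adjusted over the list alone (median 0.04, list-test adjusted p 0.000110). HNRNPR (0.16, SE 0.03) and the helicase DDX5 (0.19, SE 0.04) were positive, and MBNL1, a regulator of alternative splicing in muscle, was negative (-0.23, SE 0.05) in the authors' deposited table. Of 22 SR proteins and SR kinases, 6 were called positive and 0 negative (8 positive adjusted over the list alone; median 0.01, list-test adjusted p 0.00528). They were led by SRSF1 (0.29, SE 0.04), SRSF2 (0.29, SE 0.04), SRSF6 (0.24, SE 0.06) and SRSF3 (0.18, SE 0.06) in the authors' deposited table. With ranks in place of the statistic the SR list did not pass (adjusted p 0.220). Of 53 core spliceosome genes, SF3B4 (0.22, SE 0.07) and SNRPG (0.15, SE 0.05) were called (1 adjusted over the list alone), with a list-test adjusted p of 0.172. Whether splicing-regulator and core spliceosome lists differed from each other was not tested.

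Other RNA processing lists did not pass. Among 22 genes of mRNA 3' end processing, CLP1 was called positive (0.59, SE 0.15) and SYMPK negative (-0.18, SE 0.07) in the authors' deposited table, as also when adjusted over the list alone. The list-test adjusted p was 0.645, and the sign of the list's median (-0.01) differed from that of its mean and test. CLP1 lies at 50 to 60 Mb of chromosome 11, where the median of 18 genes was 0.25. Of 24 RNA exosome and nonsense-mediated decay genes, DIS3 (0.19, SE 0.07) and EXOSC10 (0.14, SE 0.05) were called (3 adjusted over the list alone; list-test adjusted p 0.212). DIS3 lies on chromosome 13, where the median fold was 0.11.

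Stress response genes leaned negative. Of 40 tested genes of the unfolded protein and integrated stress response, 18 were called negative and 3 positive (19 and 4 adjusted over the list alone), with a median log2 fold of -0.11 and a list-test adjusted p of 6.31e-09. The pseudokinase TRIB3 (-0.59, SE 0.06), the mTORC1 inhibitor DDIT4 (-0.51, SE 0.05), the secreted hormone STC2 (-0.37, SE 0.04) and the serine synthesis enzyme PHGDH (-0.36, SE 0.06) had the smallest p-values in the authors' deposited table. Of the 40, 4 lie in leaning segments of chromosomes 11, 13 and 22; without those segments the list-test adjusted p was 1.06e-08. Of 23 p53 target genes, 5 were called negative and 0 positive (6 negative adjusted over the list alone; median -0.03, list-test adjusted p 0.0387). Among them were GDF15 (-0.74, SE 0.09), the cell cycle inhibitor CDKN1A (-0.40, SE 0.08), GADD45A (-0.36, SE 0.08) and SESN2 (-0.25, SE 0.10) in the authors' deposited table. SESN2 belongs to the stress response list as well, so the lists are not independent. MDM2 (-0.05, SE 0.08) and BAX (0.02, SE 0.09), named outside the rule, were not called. The p53 list did not pass at a preset correlation of 0.05 (adjusted p 0.194), with ranks (0.371), at a level of at least 100 (0.0568) or with a signed z (0.0843).

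The immediate early and AP-1 list and the lipid synthesis list also leaned negative. Of 28 immediate early and AP-1 genes, 6 were called negative and 2 positive (9 and 2 adjusted over the list alone; median -0.06, list-test adjusted p 0.000534). PHLDA1 (-0.63, SE 0.04), the phosphatase DUSP5 (-0.56, SE 0.06) and KLF6 (-0.35, SE 0.05) were negative, and JUN was positive (0.29, SE 0.05) in the authors' deposited table. None of the 6 negative calls was a FOS or JUN family gene. Outside the rule for named genes, JUNB was the other positive call (0.18, SE 0.07). FOS (0.01), FOSB (0.03), EGR1 (0.07) and IER2 (0.12) had positive folds without a call. JUND (-0.12), FOSL1 (-0.08) and FOSL2 (-0.04) had negative folds without a call. Of 20 genes of fatty acid synthesis and lipid storage, 4 were called negative and 0 positive (5 and 1 adjusted over the list alone; median -0.07, list-test adjusted p 0.000963). They were the lipogenic transcription factor SREBF1 (-0.34, SE 0.05), the desaturase SCD (-0.19, SE 0.03), the elongase ELOVL6 (-0.57, SE 0.11) and the lipid droplet protein PLIN2 (-0.29, SE 0.06) in the authors' deposited table. The 24 cholesterol synthesis genes were split, with 3 called in each direction, also when adjusted over the list alone (list-test adjusted p 0.515). INSIG1 was negative (-0.38, SE 0.05) and ACAT2 positive (0.22, SE 0.07) in the authors' deposited table.

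Heat shock, ribosomal and neuronal lists passed with less support. Of 17 heat shock genes, 5 were called positive and 0 negative (5 and 1 adjusted over the list alone; median 0.02, list-test adjusted p 0.0345), including DNAJA1 (0.25, SE 0.05), HSPH1 (0.29, SE 0.05), HSPA8 (0.15, SE 0.04) and BAG3 (0.18, SE 0.06) in the authors' deposited table. HSPH1 lies on chromosome 13; the list did not pass without those segments of chromosomes 11, 13 and 22 (adjusted p 0.130), at a correlation of 0.05 (adjusted p 0.147), with ranks (0.177) or with a signed z (0.0843). Of 73 cytosolic ribosomal protein genes, 5 were called negative and 1 positive, also when adjusted over the list alone (median -0.03, list-test adjusted p 0.0345). The ribosomal list did not pass at a correlation of 0.05 (adjusted p 0.317), at a level of at least 100 (0.0597), with centred folds (0.0564) or with a signed z (0.0843). It passed without the segments and with ranks (list-test adjusted p 0.00129 with ranks). RPL28 (-0.21, SE 0.04) and RPL3 (-0.18, SE 0.04) were negative and RPL21 positive (0.17, SE 0.03) in the authors' deposited table. RPL21 lies on chromosome 13 and RPL3 in the negative segment of chromosome 22, where the median fold was -0.06. Of 10 neuronal genes tested, 3 were called negative and 1 positive, also when adjusted over the list alone (median -0.02, list-test adjusted p 0.00579, or 0.323 with ranks). UCHL1 (-0.32, SE 0.03), TUBB3 (-0.33, SE 0.06) and SYT1 (-0.71, SE 0.14) were negative and SYP positive (0.39, SE 0.15) in the authors' deposited table.

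**Figure D2:**
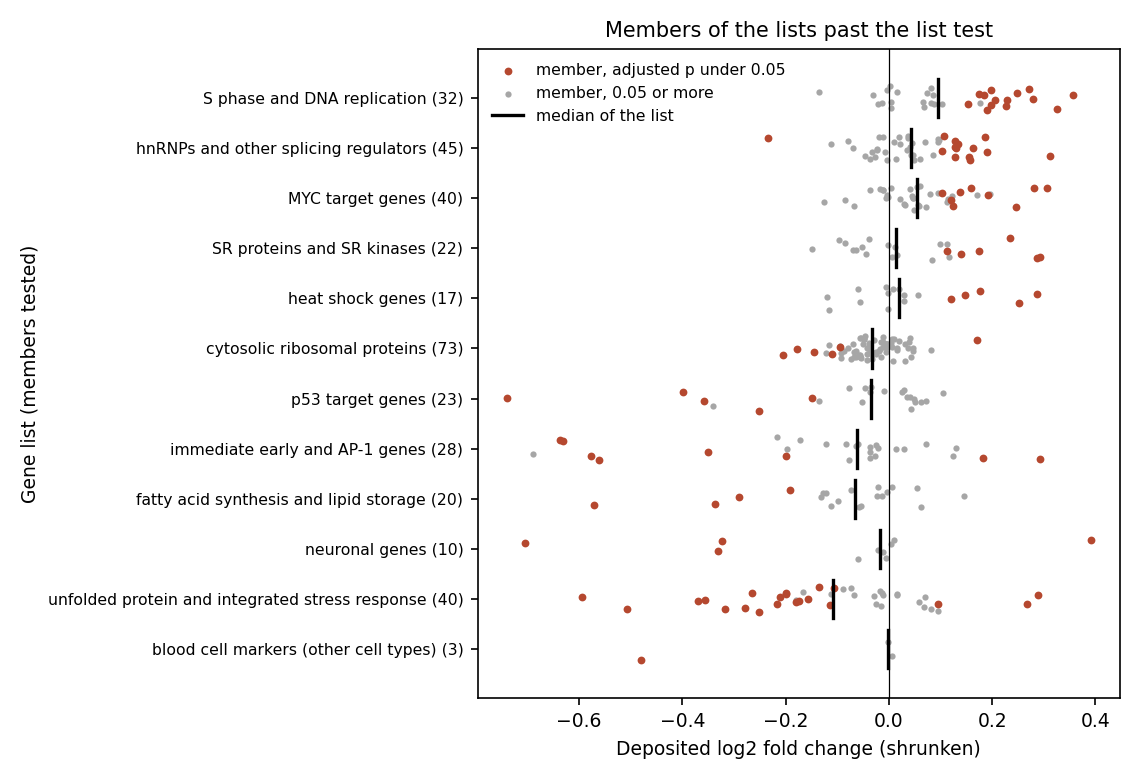
Each point is the deposited log2 fold of 1 member of a gene list that passed the list test, red where its adjusted p was under 0.05; black bars are list medians and the number of members tested is in brackets (points are spread vertically for legibility). The S phase list has its median at 0.10 and the stress response list at -0.11, while the blood cell list rests on 1 of its 3 members.

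Matrix and mesenchymal genes were called in both directions. Of 33 collagen and matrix genes, 8 were called positive and 6 negative (9 and 9 adjusted over the list alone; list-test adjusted p 0.1004); its median was -0.01 while its mean (0.08) and test leaned positive. In the authors' deposited table COL11A1 (0.68, SE 0.04), COL3A1 (0.75, SE 0.06) and COL5A2 (2.02, SE 0.14) were positive and the laminin LAMB3 negative (-1.05, SE 0.14). Of 24 mesenchymal genes, 4 were called positive and 6 negative, also when adjusted over the list alone (list-test adjusted p 0.172). The mean of that list was 0.17 and its median -0.03, while the test leaned negative. THY1, the member with the largest fold (3.54, SE 0.66), pulled the mean up. With the log2 fold in place of the statistic at a level of at least 100, the list passed in the positive direction (adjusted p 0.0387). VIM (-0.23, SE 0.03), ITGB3 (-0.50, SE 0.08) and CDH2 (-0.36, SE 0.06) were negative and TGFBI positive (0.53, SE 0.09) in the authors' deposited table. Of 22 TGF-beta targets, 4 were called positive and 5 negative (10 and 5 adjusted over the list alone; list-test adjusted p 0.835), with ID1 (-0.33, SE 0.06) and TGIF1 (-0.29, SE 0.05) on the negative side in the authors' deposited table. Of 24 YAP and TEAD targets, 3 were called positive and 6 negative (4 and 6 adjusted over the list alone; list-test adjusted p 0.587). They included CCN2 (-0.35, SE 0.07), NT5E (-0.32, SE 0.05), CCN1 (-0.20, SE 0.05) and PTPN14 (0.16, SE 0.04) in the authors' deposited table.

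Interferon and inflammatory genes had calls on the negative side without passing as lists. Of 43 interferon-stimulated genes, 6 were called negative and 0 positive, also when adjusted over the list alone (list-test adjusted p 0.188). In the authors' deposited table IFITM2 had a log2 fold of -0.86 (SE 0.14), IFI44L -0.50 (SE 0.20), IFIT2 -0.33 (SE 0.13) and PSMB8 -0.07 (SE 0.15, adjusted p 0.00863), the last with a fold smaller than its error. With a signed z from the p-value the interferon list passed (adjusted p 0.0487). Of 24 NF-kB and inflammatory genes, 4 were called negative and 0 positive (7 and 1 adjusted over the list alone; list-test adjusted p 0.104): SOD2 (-0.31, SE 0.04), IL6 (-0.68, SE 0.18), ICAM1 (-0.59, SE 0.18) and IRAK2 (-0.26, SE 0.11) in the authors' deposited table.

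Liver genes were mostly at low levels. Of 38 hepatocyte genes, 8 had an adjusted p, and 31 had a mean level under 10 normalized counts. Among list members outside the rule for named genes, chosen after the data were seen, ALB had a mean level of 0.733, APOA1 of 0.178 and HNF4A of 0.373 in the authors' deposited table, against 91782 for VIM. FGB, the fibrinogen beta chain, was called (0.60, SE 0.09, level 1719), while FGG was at 0.07 (SE 0.12); the list-test adjusted p was 0.188. Among 17 blood cell markers 14 had a mean level under 10, and PTPRC, chosen in the same way, stood at 3.44 in the authors' deposited table. The blood list passed (adjusted p 0.0314) on 3 tested members, of which CD68, a lysosomal protein found beyond macrophages, was called (-0.48, SE 0.06, level 3092), also when adjusted over the list alone. The blood list did not pass with ranks (adjusted p 0.528) or with a signed z (adjusted p 0.0779). CD14 and CSF1R were at 0.01 (SE 0.11) and -0.00242 (SE 0.11) in the authors' deposited table. Of 7 endothelial markers tested, 0 were called by the adjusted p or over the list alone (list-test adjusted p 0.656), and EGFL7 (0.33, SE 0.37, level 142) and ENG (0.07, SE 0.06, level 2908) had the smallest p-values in the authors' deposited table.

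Of the 38 lists, 12 passed the limma list test. That test sets genes against other genes within 1 comparison, so it does not show that a shift recurs across samples. At a preset correlation of 0.05 between genes, 9 of them passed, and the correlation itself could not be estimated without values per sample. With the log2 fold in place of the statistic at a level of at least 100, the S phase list was the 1 list of the 12 that passed.

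Folds also differed by position. Of 24 chromosomes, the mitochondrial genome included, 7 had a median that differed from random lists matched on level (adjusted p under 0.05). Of 253 windows of 10 Mb, 20 did, 10 in each direction. The random lists treat neighbouring genes as independent. Most of these chromosome medians were small: -0.01 for chromosome 1, 0.01 for 7 and 11, -0.02 for 12 and 19, and -0.04 for 22. Chromosome 13 had the largest median, 0.11, with 160 of 183 genes positive in the authors' deposited table. Without chromosome 13, chromosome 11 at 50 to 60 Mb and chromosome 22 below 40 Mb, segments chosen after the data were seen, 1279 rows were called, 548 positive and 731 negative.

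**Figure D3:**
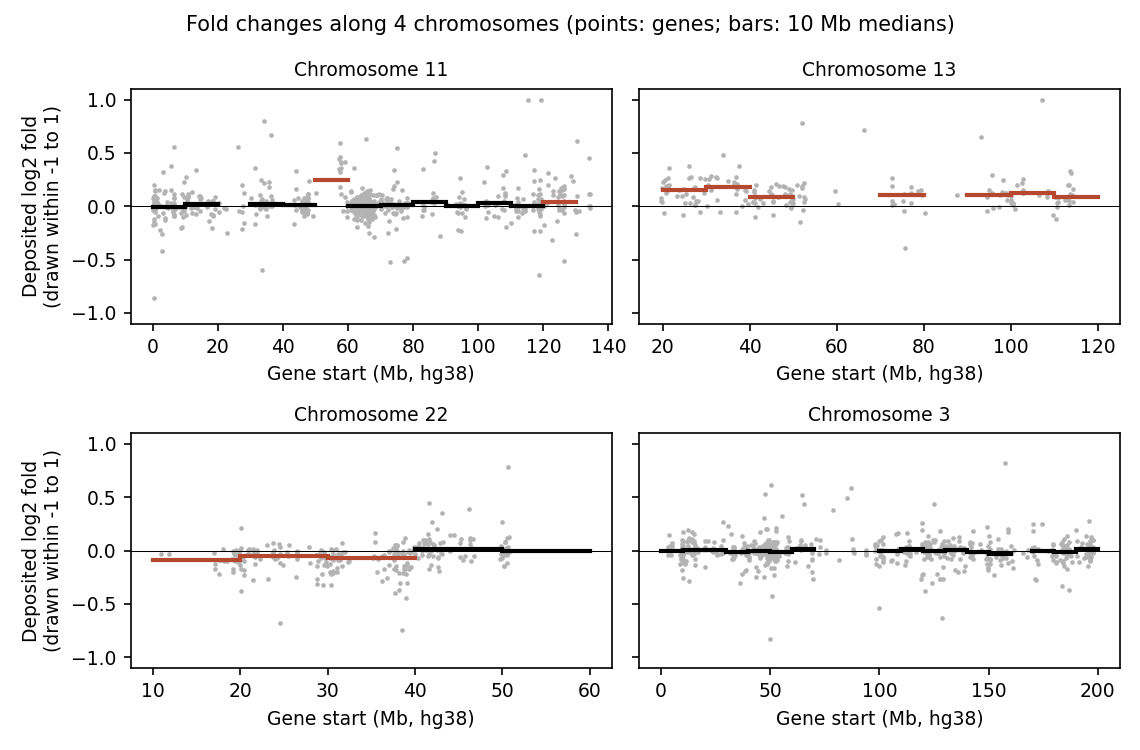
Deposited log2 folds of genes at a mean level of at least 100 (grey points, drawn within -1 to 1) by gene start in Mb on hg38 for chromosomes 11, 13, 22 and 3; bars are medians of 10 Mb windows, red where past the random-list threshold. The bars lie above 0 along chromosome 13, at 0.25 for 50 to 60 Mb of chromosome 11, below 0 for chromosome 22 under 40 Mb, and near 0 on chromosome 3, which holds SMARCC1.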

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

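The counts were similar (within 1.5 times) at an adjusted p under 0.1, at a mean level of at least 10 or 100, with adjustment over every p-value, and in the settings added after the data were seen, 1 row per symbol and without the 3 segments of chromosomes 11, 13 and 22; these gave 1225 to 1775 calls against 1372. At an adjusted p under 0.01 there were 861 calls (364 positive, 497 negative). Requiring at least 1.5-fold left 272 (154 positive, 118 negative; 56.6% positive) and at least 2-fold left 131 (87 positive, 44 negative; 66.4% positive), against 43.9% positive in the main count; the deposited folds appear shrunken, which by construction lowers the number that reach a fold threshold. The deposited fold of SMARCC1, 0.53, stayed past the adjusted p threshold in every setting run and lies below both the 1.5-fold and the 2-fold requirement. Of 12 gene lists that passed, 9 passed at a correlation of 0.05, 10 lists passed at a level of at least 100 (9 of the 12 and the hepatocyte list), 11 with centred folds, 9 with a signed z (8 of the 12 and the interferon list) and 11 without the segments. With ranks 7 passed, all among the 12. With the log2 fold at a level of at least 100 only 2 passed, the S phase list and the mesenchymal list. The mesenchymal list turned from negative without passing (list-test adjusted p 0.172) to positive (adjusted p 0.0387). Among its members at that level THY1 had a fold of 3.54 (SE 0.66), and the next positive fold was 0.53 (TGFBI). The positive result therefore leans on THY1, and the list without THY1 was not tested. The blood cell list had too few members at a level of at least 100 for a test there. The hepatocyte list had 3 members at that level and rested on FGB (0.60, SE 0.09). FGG (0.07, SE 0.12) and CPS1 (0.02, SE 0.10), the latter named outside the rule, were not called. None of the 12 lists changed direction in a setting that tested it. Of the lists that did not pass, the collagen, Notch and WNT lists changed sign with ranks, the WNT list also with centred folds, the TGF-beta list at a level of at least 100 and the fetal liver list with a signed z, none of them past the threshold. No paired analysis was possible because the table holds no values per sample, although the labels share batch numbers between the groups. For the same reason the planned batch term, other count model, other size factors, low-count filter, pseudocounts, leaving out of each replicate and the count of other splits of the samples were not run, and no gene was checked for dependence on 1 library. Low levels leave 6270 rows with a p-value and no adjusted p, and 112 of the called rows had a level under 100.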

Other observations

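The tests on the SMARCC1 segment, on lentiviral amount, on regulation along chromosome 13 and on the G2/M list were chosen after their results had been seen; so were the patterns themselves and the segments. Among the fixed lists not described in the report, 7 of 33 hypoxia and glycolysis genes were called negative and 3 positive (also adjusted over the list alone; list-test adjusted p 0.171), with the glucose transporter SLC2A3 at -0.49 (SE 0.07) and P4HA2 at -0.32 (SE 0.07). Glycolysis genes were called on both sides. PFKFB3 (0.43, SE 0.07) and PGAM1 (0.18, SE 0.04) were positive in the authors' deposited table. HK2 (-0.23), ENO2 (-0.28), GPI (-0.19) and HK1 (-0.20), named outside the rule, were called negative. Of 21 NRF2 antioxidant genes, 3 were called negative and 1 positive (4 and 2 adjusted over the list alone; list-test adjusted p 0.515), with TXNRD1 at -0.18 (SE 0.06), FTH1 at -0.12 (SE 0.03) and GCLM at 0.24 (SE 0.06). In the Notch list JAG1, a Notch ligand, was the 1 of 12 genes called, also adjusted over the list alone (-1.30, SE 0.08, adjusted p 5.36e-53; LFNG 0.15, SE 0.08; list-test adjusted p 0.130), and the list's median (0.01) and mean (-0.10) differ in sign. Of 13 mitochondrially encoded mRNAs, 3 were called negative and 1 positive (3 and 3 adjusted over the list alone; list-test adjusted p 0.410): MT-ND4 (-0.22, SE 0.06), MT-ND5 (-0.19, SE 0.06), MT-CO2 (-0.20, SE 0.06) and MT-CO3 (0.09, SE 0.03) in the authors' deposited table.

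The remaining lists had 2 or fewer calls and did not pass. Of 47 nuclear oxidative phosphorylation genes, NDUFS1 was called (-0.14, SE 0.05), with 0 calls adjusted over the list alone and a list-test adjusted p of 0.310; ATP5MC1 stood at 0.19 (SE 0.08). Epithelial genes gave 2 negative calls of 14 tested, KRT18 (-0.08, SE 0.03) and ELF3 (-0.31, SE 0.16), the same adjusted over the list alone (list-test adjusted p 0.656). In the fetal liver, progenitor and biliary list SOX4 was the 1 positive call of 10, also adjusted over the list alone (1.12, SE 1.51, level 15.6), with LIN28B at -0.15 (SE 0.08) and a list-test adjusted p of 0.813; its median (0.01) and its test differ in sign. Of 17 antigen presentation genes PSMB8 was the 1 called, also adjusted over the list alone (list-test adjusted p 0.503). Its primary row had a level of 46.2. Those of HLA-B and HLA-C were at 13.1 and 79.4, against 7267 for B2M (all 3 named outside the rule). Such low rows may hold only part of a gene's reads, since rows on other contigs were not added. Histone genes (23 tested), WNT targets (6) and metallothioneins (3) had 0 calls by the authors' adjusted p or over the list alone, with list-test adjusted p of 0.515, 0.991 and 0.739; the WNT median (-0.01) and test differ in sign. Below a level of 100, and chosen after their values were seen, SYBU (6.15, SE 1.16), LCP1 (4.96, SE 0.77), RILP (-6.77, SE 2.68) and LRRK2 (-2.57, SE 0.41) had large folds in the authors' deposited table. Also chosen after being seen, 8 of 28 tested protocadherin symbols were called (6 positive, 2 negative), 9 of 24 genes at 100 to 110 Mb of chromosome X were called, all 9 negative, and 4 of 29 at 20 to 30 Mb of chromosome 19, where 21 symbols start with ZNF, all 4 positive.

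Fold signs followed chromosome segments. On chromosome 13, 160 of 183 genes at a level of at least 100 had a positive fold (87.4%, 95% exact interval 81.7 to 91.9; median 0.11) and 40 of 41 called genes were positive; at 50 to 60 Mb of chromosome 11, 9 of 18 genes were called, all 9 positive (median 0.25), and below 40 Mb of chromosome 22, 142 of 175 genes were negative (81.1%) with 30 of 30 calls negative. The called genes of the chromosome 11 segment lie between 57299638 and 57819546, except FAM111B (start 59107185), named outside the rule. Genes at 60 to 70 Mb of that chromosome had a median of 0.00359. The medians of chromosomes 11, 13, 19 and 22 had a random-list p of 0.0002, the smallest that 10000 draws can give. GC content and transcript length did not account for chromosome 13, whose median was 0.11 before and 0.12 after their trend was removed, against -0.01 to 0.02 in random lists. A candidate explanation is a difference in copy number between the cells of the groups. Among genes at a level of 10 to 100, set aside for the test, the leaning share on chromosome 22 was 70.5% (54.8 to 83.2, 44 genes), as it predicts. That share cannot favour copy number, since any cause acting along the segment would give it. The chromosome 22 median was -0.06 at a level of at least 100 and -0.01 at 10 to 100. The share was 65.6% on chromosome 13 (46.8 to 81.4, 32 genes) and 62.5% on chromosome 11 (24.5 to 91.5, 8 genes), too few genes to tell. All 7 of 7 windows of chromosome 13 leaned positive, which copy number and a uniform regulation by BAF155 would both give, so these cannot be told apart there.

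SMARCC1 had a deposited log2 fold of 0.53 between 2 groups that both re-express it. A copy number difference of its segment would move its neighbours, whose median at 40 to 50 Mb of chromosome 3 was -0.00248 (95% bootstrap interval -0.03 to 0.01, 79 genes), which argues against it. A difference in the amount of lentiviral transcript, unrelated to the substitution, may give the same 0.53, and it cannot be told apart from an effect of R1064K because lentiviral and endogenous reads share a row. Other differences between the groups therefore could reflect the dose of BAF155 as well as its methylation, and no value in the table separates these. Differences between the cells of the groups, such as the copy number difference raised above, could also reach genes outside the segments. They were not tested for those genes.

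S phase genes were positive (median 0.10) and stress response genes negative (median -0.11). A larger share of dividing cells would raise G2/M genes with the replication genes, but the G2/M median was 0.00529 (95% bootstrap interval -0.03 to 0.03, 29 genes), less than the change to be explained. GC content and length left at least 93.6% of either median (0.10 for replication and -0.10 for stress after correction), and leaving out the 3 segments of chromosomes 11, 13 and 22 left at least 100% (0.13 and -0.11); other windows past the threshold, such as 10 to 20 Mb of chromosome 19, stayed in. A response to the methylation state or the amount of BAF155, a longer S phase, growth conditions and culture density stay open and were not tested. The same holds for other differences between the cells of the groups, including copy number outside the 3 segments.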
